A study of Homo sapiens with 6 samples.

How the data were processed

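RNA was sequenced from 6 cultures of ME180, a human cervical cancer cell line of epithelial morphology, 48 h after transfection with a control small interfering RNA (siControl, 3 libraries) or with one against the serum and glucocorticoid regulated kinase SGK1 (siSGK1, 3 libraries). The series describes the 3 libraries of each group as biological repeats. Libraries were made from polyA RNA isolated with TRIzol, using the NEBNext Ultra RNA kit, per the labels' protocols. The sequences of the siRNAs are not given in the sources used here.

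The deposited values are FPKM (fragments scaled to gene length and library size) for 58302 genes, with 1 column per library and with each gene's name, position, length and biotype. Per the submitters' processing notes, the tools were bcl2fastq 2.19, HISAT2 2.0.5 and featureCounts 1.5.0-p3, and the genome build was hg19. The gene coordinates in the table are nevertheless those of GRCh38: of 57980 gene identifiers shared with the GENCODE 29 basic annotation of GRCh38, 56588 (97.6%) had the same chromosome, start, end and strand. All positions printed here are the table's own and are read as GRCh38. The strand setting and the treatment of reads that map to several places are not given in the sources used here, so a gene and an overlapping or antisense partner, or near-identical gene copies, may share reads. Among the genes that the rule below picks and the text gives values for, exons overlap those of another tested gene for SGK3 (C8orf44), MT-CO3 (MT-ATP6), NDUFS1 (EEF1B2), SCNN1A (LTBR), BAD (GPR137) and HSPD1 (HSPE1). Exons of untested genes overlap those of SGK2, SPINK13, TPM4, ISG15, IGFL1, ALDH3A1, TSC22D3, IER2, CDKN1A, MCL1, DDIT4, RRM2, KRT15, LAMB3, THBS1, ALDOC, SLC2A1, TRPV6, TRPV4, SLC6A6, AGO2 and RPL30, so the values of all these genes are uncertain to that extent.

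Depth was recovered from the values. In each library, deposited FPKM multiplied by gene length was a whole multiple of a single step for 100% of values above 0, within a tolerance of 0.001, so the table holds whole reads: 27262794 to 35242643 per library. The library size implied by the step was 0.952 to 1.09 times that total, and equalled the median-of-ratios size factor over 19967 genes times the geometric mean of the totals. The deposited FPKM therefore already carry a scaling by size factors, which sets the typical gene to be close to unchanged.

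Values were tested as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, two-sided), siSGK1 against siControl, with Benjamini-Hochberg adjustment over the 11945 genes whose mean FPKM was at least 1. A gene was called at an adjusted p below 0.05. Fold changes on the log2(FPKM + 0.5) scale understate the change of low genes. All adjusted p-values of genes are from this limma test unless another setting is named. Beside it, the SGK1 values were compared by an exact permutation test. Gene lists (28) were tested with limma's camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists with at least 5 tested members. Camera was also run with an estimated correlation, and limma's fry gave a test of each list's own direction. The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes are SGK1, SGK2 and SGK3, then the 12 largest rises and 12 largest falls among called protein-coding genes with a mean FPKM of at least 5 and no overlap between groups, and up to 4 tested members of each list with the smallest p. Any other gene named was chosen after its values were seen, and the text says so. Some genes that this rule names are not reported here.

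The longest annotated 3' UTR of each protein-coding gene was taken from GENCODE 29. Of 10394 tested protein-coding genes, 10271 had one of at least 50 bases. For each of 15630 heptamers found in at least 100 of these genes, the log2 change was regressed on its presence, with UTR length, base composition, CpG share and mean level as covariates, and p was Bonferroni-adjusted over heptamers. Genes are not independent replicates, so these p-values rank sequences and do not test the conditions. The octamers, the classes of sites and the comparison with heptamers of the same bases were chosen after the search had been seen. The search used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

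The main limma test and the heptamer search were tried on simulated or shuffled data first. Simulated genes varied independently around a single dispersion, with 50 changed at each fold. The rates below therefore need not hold for the real libraries. For simulated siSGK1 against siControl over 11939 genes, the limma test recovered 52% of genes changed 1.25-fold, 90% of those changed 1.5-fold, 100% of those changed 2-fold and 96% of those changed 3-fold, and called 0.13% of unchanged genes. The shares of changed genes are of all 50 at each fold, of which 49 at 1.5-fold and 48 at 3-fold passed the level filter. A planted heptamer lowering 3' UTR carriers by 0.2 log2 units ranked first among all heptamers over 10271 genes. With shuffled genes the strongest absolute t was 3.68.

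Alternatives were other pseudocounts (0.1 and 1), other filters (none, or mean FPKM at least 5), median-ratio and quantile normalization, limma without the trend or with robust eBayes, voom on the recovered reads, the replicate number as a block, removal of a trend on gene length, protein-coding genes alone, and leaving out each library in turn. Scaling by total reads, TPM scaling, removal of a trend on GC, leaving out genes with a 3' UTR site, and the differentiation list without keratins and SPRR genes were added after the data had been seen. No library was left out of the results reported first.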

Results

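Gene expression was measured by polyA RNA sequencing in ME180 cervical cancer cells 48 h after transfection with a control siRNA (siControl) or an siRNA against SGK1 (siSGK1), with 3 biological repeats of each, numbered 2, 3 and 4. SGK1 is a serine/threonine kinase related to AKT that regulates ion channels and transporters. The siControl libraries held 27262794 to 27874948 reads assigned to genes, and the siSGK1 libraries held 28405647 to 35242643. Mitochondrially encoded genes took 4.25% ± 0.13 of reads in siControl and 3.5% ± 0.14 in siSGK1 (SD, n = 3 each). The 50 genes with most reads took 20.1% ± 0.08 and 16.9% ± 0.57. No pair of libraries of a group agreed within counting noise, as copies of a single library would (chi-square per degree of freedom between 3.31 and 8.35 for the 6 pairs).

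The targeted transcript was lower in every siSGK1 library. SGK1 (ENSG00000118515, chromosome 6, 134169246 to 134318112, minus strand) fell from 4.12 ± 0.19 FPKM in siControl to 1.70 ± 0.12 FPKM in siSGK1 (SD, n = 3 each), which is 41.2% of the control level. Its log2 change was −1.07 (SE 0.07, adjusted p = 1.88e-05). The reads behind these values were 1024, 1108 and 1123 in siControl and 463, 562 and 663 in siSGK1. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. SGK3 (chromosome 8, 66712418 to 66862022) lay below the level filter and was tested only without it. It measured 1.00 ± 0.14 FPKM in siControl and 0.54 ± 0.04 FPKM in siSGK1 (log2 change −0.53, limma adjusted p = 0.026 without the filter). Its 3' UTR contains the octamer CTATGCAA described at the end of this section, and it shares exon sequence with C8orf44, so its value is uncertain. SGK2 had 0 to 2 reads per library, too few for a comparison.

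**Figure D1:**
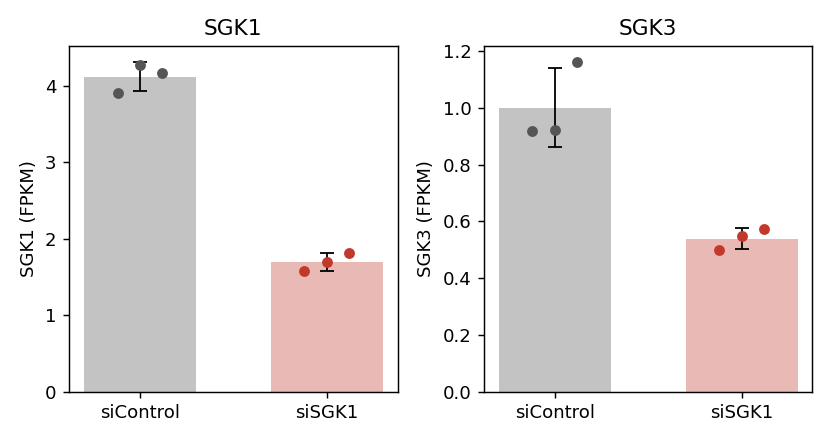
SGK1 (left) and SGK3 (right) in FPKM for siControl and siSGK1; bars are group means, error bars are SD, and points are the 3 libraries of each group. SGK1 fell from a mean of 4.12 to 1.70 FPKM, and SGK3, tested only without the level filter, from 1.00 to 0.54 FPKM, with no overlap between groups.

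Transfection with siSGK1 was followed by many changes, most of them small. Of 11945 tested genes, 4852 were called, 2143 higher and 2709 lower. With a fold of at least 1.5, 285 were higher and 442 lower. At an unadjusted p under 0.05 there were 5868 genes. The share of called genes that were higher was 44.2% as deposited, 51.2% under quantile normalization, 73.6% when libraries were scaled by total reads and 82.8% under TPM scaling. The median of all genes lay at −0.006 log2 units as deposited, at 0.12 with total-read scaling and at 0.19 with TPM scaling, so each direction is relative to the median gene. Along the first principal component, which held 67.9% of the variance, all siControl libraries lay on the other side from all siSGK1 libraries.

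Keratins, aldehyde dehydrogenases and HMOX1 were among the largest falls. KRT1, a keratin of suprabasal epidermis (chromosome 12, 52674736 to 52680407), fell 6.51-fold, from 9.12 ± 0.58 to 1.40 ± 0.06 FPKM (log2 change −2.34, SE 0.06, adjusted p = 8.93e-07). Its partner KRT10 fell from 275.0 ± 10.8 to 92.0 ± 1.3 FPKM, and KRT16, a keratin of activated keratinocytes, from 390.3 ± 16.1 to 117.6 ± 9.5 FPKM. KRT6C fell from 8.90 ± 0.45 to 2.75 ± 0.75 FPKM, a value that is uncertain because KRT6A and KRT6B are near-identical copies. IGFL1, an insulin growth factor-like protein, fell 5.33-fold, and CEND1, named for cell cycle exit and neuronal differentiation, fell 4.55-fold. The aldehyde dehydrogenases ALDH3A1 and ALDH3B2 fell 3.19-fold and 2.82-fold. HMOX1, the inducible heme oxygenase, fell 3.24-fold. The other large falls were GAST (gastrin, 3.30-fold), ZDHHC1 (a palmitoyltransferase, 3.07-fold) and the metalloproteinase MMP28 (2.82-fold). Of these 12 genes, ZDHHC1 has the octamer CTATGCAA in its 3' UTR, and the other 11 have neither it nor its heptamers. The 3' UTR of KRT1 contains CGGAGAA, a heptamer found in genes that were higher. ALDH3A1 and IGFL1 overlap antisense exons.

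Genes of a serine peptidase inhibitor cluster and interferon-induced genes were among the largest rises. AC011346.1 (chromosome 5, 148221650 to 148243580) rose 4.77-fold, from 4.56 ± 0.79 to 21.7 ± 2.4 FPKM (log2 change 2.14, SE 0.11, adjusted p = 9.28e-06). The next gene downstream, SPINK13 (148268180 to 148286254), rose from 2.00 ± 0.72 to 9.04 ± 1.84 FPKM. It overlaps the antisense gene AC091948.1. TPM4, a tropomyosin, rose 3.16-fold, from 37.3 ± 4.0 to 118.1 ± 7.1 FPKM, and its 3' UTR contains another octamer, TCGGAGAA, described at the end of this section. KRTAP3-1, a hair keratin-associated protein, rose 3.11-fold, and CYR61, a secreted matrix-associated protein, rose from 13.2 ± 2.0 to 35.3 ± 2.4 FPKM. OGFR (opioid growth factor receptor), GANAB (a glucosidase of the endoplasmic reticulum) and NOLC1 (a nucleolar phosphoprotein) rose 2.43-fold, 2.40-fold and 2.26-fold. The 3' UTR of NOLC1 contains TCGGAGA and TATGCAA. The other 4 were the interferon-induced genes IFI6, IFI27, ISG15 and IFIT1.

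**Figure D2:**
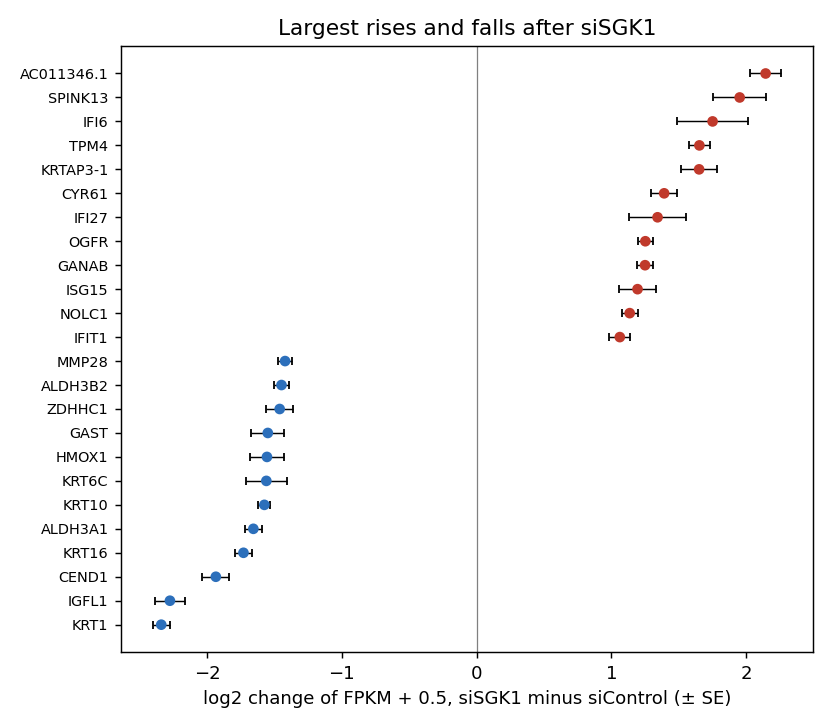
Log2 change of FPKM + 0.5 (siSGK1 minus siControl, horizontal axis) for the 12 largest rises (red) and 12 largest falls (blue) among called protein-coding genes; points are limma estimates and bars are SE. Changes run from −2.34 for KRT1 to 2.14 for AC011346.1.

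Genes of keratinocyte differentiation fell almost throughout. Of 28 tested members 27 fell and 0 rose, with the same counts when adjusted over the list alone, and the mean log2 change was −0.91. Besides KRT1, KRT10 and KRT16, the antimicrobial protein S100A7 fell from 6.76 ± 0.26 to 2.29 ± 0.05 FPKM. Camera called the list lower at adjusted p = 2.72e-15; adjusted p = 0.23 with an estimated correlation, which did not pass. Basal keratinocyte and junction genes were also lower as a list: 17 of 26 tested members fell and 1 rose (18 and 1 adjusted over the list alone; adjusted p = 5.09e-06; adjusted p = 0.23 with an estimated correlation). KRT14, a keratin of the basal layer, fell from 1388 ± 29 to 541.2 ± 54.8 FPKM. KRT15 fell from 272.3 ± 8.4 to 145.6 ± 9.7 FPKM, the laminin chain LAMB3 from 53.2 ± 4.1 to 28.1 ± 1.8 FPKM, and the desmosomal cadherin DSG3 from 14.9 ± 0.9 to 9.71 ± 0.43 FPKM. The keratins KRT14 and KRT16 are close in sequence, so some of their reads may be shared.

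Genes of G2 and mitosis were higher. Of 23 tested members 20 rose and 0 fell, as they did adjusted over the list alone, with a mean log2 change of 0.55 (adjusted p = 3.14e-12; adjusted p = 0.23 with an estimated correlation). AURKB, a mitotic kinase, rose from 26.6 ± 1.5 to 52.8 ± 1.5 FPKM. Its partner BIRC5 (survivin) rose from 27.9 ± 1.2 to 55.3 ± 2.6 FPKM, the ubiquitin-conjugating enzyme UBE2C from 98.9 ± 3.9 to 167.6 ± 2.9 FPKM, and the spindle protein TPX2 from 35.3 ± 0.5 to 53.5 ± 0.4 FPKM. Of the genes of DNA replication and G1/S, 13 of 26 rose and 5 fell (14 and 5 adjusted over the list alone), with a mean log2 change of 0.12 (adjusted p = 0.022; adjusted p = 0.23 with an estimated correlation). The estimated correlation of this list was −0.02, below the preset 0.01, so the lost call does not come from a higher correlation within the list. RRM2, a subunit of ribonucleotide reductase, rose from 8.71 ± 0.20 to 15.2 ± 0.5 FPKM, and CDC45, a part of the replicative helicase, from 10.2 ± 0.4 to 14.1 ± 0.5 FPKM. The list of G1 cyclins, CDKs and CDK inhibitors was not called (5 of 15 tested members rose and 3 fell, the same adjusted over the list alone; adjusted p = 0.39). Within it CDK6, whose 3' UTR contains CGGAGAA, rose from 1.47 ± 0.12 to 2.97 ± 0.37 FPKM, and the CDK inhibitor CDKN1A fell from 264.3 ± 23.9 to 178.2 ± 10 FPKM.

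Type I interferon response genes were higher. Of 22 tested members 19 rose and 1, the transcription factor IRF1, fell (20 and 1 adjusted over the list alone), with a mean log2 change of 0.68 (adjusted p = 3.31e-09; adjusted p = 0.26 with an estimated correlation). IRF1, chosen after its values were seen, had a log2 change of −0.24. IFI6 rose from 70.8 ± 30.9 to 224.0 ± 12 FPKM, and its control libraries spread widely, at 69.0, 102.7 and 40.9 FPKM in replicates 2, 3 and 4. IFI27 rose from 22.6 ± 7.9 to 56.0 ± 5.6 FPKM and the ubiquitin-like modifier ISG15 from 93.2 ± 19.1 to 210.9 ± 15.6 FPKM. IFIT1, which binds viral RNA, rose from 4.35 ± 0.52 to 9.60 ± 0.41 FPKM. The 2-5A synthetase family members OAS2 and OAS3 rose by log2 changes of 0.70 and 0.83. The list of NF-kappaB targets and cytokines was not called (3 of 12 rose and 3 fell, 4 and 3 adjusted over the list alone; adjusted p = 0.84). In it TNFAIP2 fell from 46.4 ± 2.3 to 28.5 ± 1.4 FPKM, and the prostaglandin synthase PTGS2, whose 3' UTR contains CGGAGAA, rose from 0.93 ± 0.06 to 1.94 ± 0.15 FPKM.

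NRF2 target genes were lower. Of 20 tested members 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a mean log2 change of −0.49 (adjusted p = 4.29e-08; adjusted p = 0.23 with an estimated correlation). The ferritin light chain FTL fell from 847.7 ± 73.2 to 473.5 ± 22.3 FPKM. The aldo-keto reductase AKR1B10 fell from 65.5 ± 1.9 to 40.8 ± 2.1 FPKM. Other antioxidant enzymes went both ways and were not called as a list (3 of 23 rose and 10 fell, 4 and 10 adjusted over the list alone; adjusted p = 0.28, and 0.049 without a level filter). The glutathione peroxidase GPX2 fell from 140.4 ± 7.1 to 73.6 ± 6.3 FPKM, while the peroxiredoxin PRDX4 rose from 43.9 ± 0.8 to 68.5 ± 1.7 FPKM.

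Transcripts of energy metabolism and ribosomes were lower relative to the median gene. Nuclear respiratory chain genes fell in 22 of 26 tested members and rose in 1 (23 and 1 adjusted over the list alone; mean log2 change −0.27; adjusted p = 8.51e-08; adjusted p = 0.26 with an estimated correlation). COX5B, a subunit of cytochrome c oxidase, fell from 411.6 ± 6.3 to 282.9 ± 9.4 FPKM, and NDUFS1, a subunit of complex I whose 3' UTR contains CTATGCA, from 8.89 ± 0.38 to 5.76 ± 0.32 FPKM. With a lower share of mitochondrial reads in siSGK1 (3.5% against 4.25%), all 13 mitochondrially encoded mRNAs fell, also adjusted over the list alone (mean log2 change −0.42; adjusted p = 3.86e-07; adjusted p = 0.44 with an estimated correlation). Cytosolic ribosomal protein genes fell in 27 of 28 tested members, as they did adjusted over the list alone (mean log2 change −0.29; adjusted p = 1.34e-09; adjusted p = 0.44 with an estimated correlation). Among them RPL30 fell from 136.6 ± 2.7 to 109.1 ± 2.0 FPKM. Quantile normalization ended the call of the mitochondrial list (adjusted p = 0.73) and of the ribosomal list (adjusted p = 0.74). It also turned the sign of MT-ND6, MT-CO3, RPS18 and RPS2, whose log2 changes were −0.49, −0.47, −0.37 and −0.36 as deposited and 0.04, 0.05, 0.002 and 0.06 after it. None of these genes was called after quantile normalization. Across all tested genes the log2 change had a Spearman correlation of −0.16 with mean log2 FPKM. Falls of lists whose calls quantile normalization ended were not separated from this trend with level. MT-CO3 and RPS2 also lost their calls without a level filter (adjusted p = 0.12 and 0.054). Genes of glycolysis and glucose uptake fell in 15 of 22 and rose in 2 (16 and 3 adjusted over the list alone; mean log2 change −0.23; adjusted p = 1.40e-03; adjusted p = 0.50 with an estimated correlation), a call that quantile normalization also ended (adjusted p = 0.46). The aldolase ALDOC, whose 3' UTR contains CTATGCA, fell from 3.82 ± 0.12 to 1.66 ± 0.12 FPKM, and the glucose transporter SLC2A1 from 62.6 ± 3.0 to 36.8 ± 2.8 FPKM.

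Genes of channels and transporters that SGK1 regulates were lower. Of 19 tested members 13 fell and 0 rose (14 and 1 adjusted over the list alone), with a mean log2 change of −0.40 (adjusted p = 4.04e-05; adjusted p = 0.23 with an estimated correlation). With a mean FPKM filter of at least 5 the list was not called (adjusted p = 0.089). SCNN1A, the alpha subunit of the epithelial sodium channel, fell from 5.09 ± 0.17 to 1.66 ± 0.15 FPKM. Its 3' UTR contains CTATGCA, and it overlaps exons of LTBR on the other strand. The calcium channels TRPV6 and TRPV4 fell from 3.86 ± 0.09 to 1.61 ± 0.17 and from 2.90 ± 0.28 to 1.32 ± 0.20 FPKM. The taurine transporter SLC6A6 fell from 12.3 ± 0.3 to 8.41 ± 0.48 FPKM.

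In the list of SGK and AKT kinases, upstream kinases and substrates, which includes SGK1 itself, 9 of 20 tested members fell and 2 rose (9 and 3 adjusted over the list alone). The list passed narrowly (adjusted p = 0.046; adjusted p = 0.44 with an estimated correlation). It was not called with a mean FPKM filter of at least 5 (adjusted p = 0.20), under quantile normalization (adjusted p = 0.056), with the GC trend removed (adjusted p = 0.10), without siSGK1 replicate 3 (adjusted p = 0.11), or without genes that have a 3' UTR site (adjusted p = 0.25). NDRG1, a phosphorylation substrate of SGK1, fell from 63.1 ± 1.2 to 39.5 ± 1.0 FPKM. The glucocorticoid-induced gene TSC22D3 fell from 21.5 ± 0.6 to 13.5 ± 0.6 FPKM. The transcription factor FOXO3, whose 3' UTR contains TATGCAA, fell from 4.56 ± 0.17 to 2.88 ± 0.09 FPKM.

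AP-1 and immediate early genes were higher by a small margin. Of 19 tested members 8 rose and 2 fell (8 and 4 adjusted over the list alone; mean log2 change 0.20; adjusted p = 0.042; adjusted p = 0.60 with an estimated correlation). The call was lost without siControl replicate 4 (adjusted p = 0.10), without siSGK1 replicate 3 (adjusted p = 0.062) and without siSGK1 replicate 4 (adjusted p = 0.095). It was also lost with a mean FPKM filter of at least 5 (adjusted p = 0.064), with total-read scaling (adjusted p = 0.060) and with TPM scaling (adjusted p = 0.054). JUN rose from 9.58 ± 0.83 to 15.6 ± 0.7 FPKM, KLF6 from 2.56 ± 0.01 to 4.17 ± 0.13 FPKM, and the phosphatase DUSP5 from 12.8 ± 1.4 to 21.1 ± 0.5 FPKM. IER2, whose 3' UTR contains TCGGAGAA, rose from 14.8 ± 0.5 to 20.1 ± 0.8 FPKM.

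**Figure D3:**
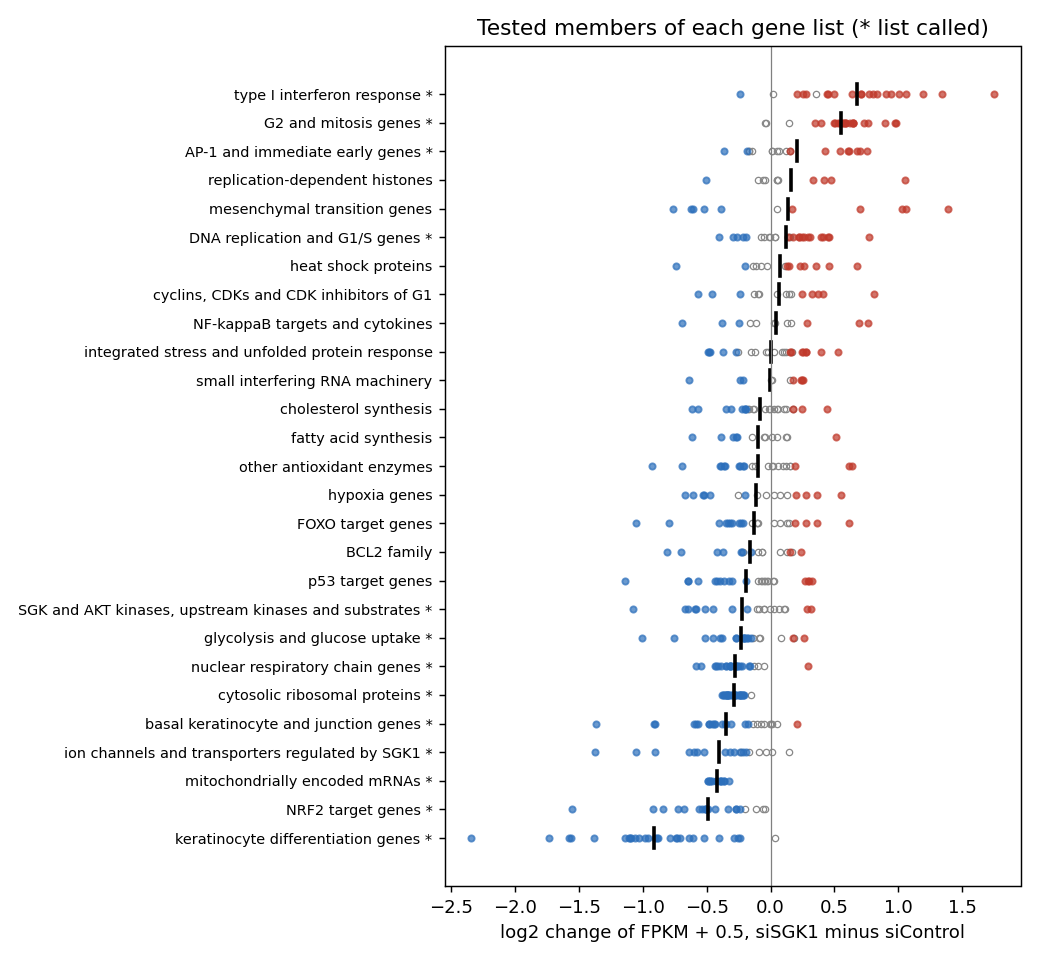
Log2 change of FPKM + 0.5 (siSGK1 minus siControl, horizontal axis) of the tested members of 27 gene lists; red points rose, blue points fell, open points were not called, the black bar is the list mean, and an asterisk marks lists called with the preset correlation. List means run from −0.91 for keratinocyte differentiation to 0.68 for the type I interferon response. Under quantile normalization the mitochondrial, ribosomal and glycolysis lists, and the list of SGK and AKT kinases, were not called. MT-ND6, MT-CO3, RPS18 and RPS2 changed sign under it, to values near 0 that were not called.

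The remaining lists held changed genes in both directions and were not called. Targets of p53 fell in 11 of 24 and rose in 4, also adjusted over the list alone (adjusted p = 0.061), and were called lower without siControl replicate 4 (adjusted p = 0.022), with voom on the recovered reads (adjusted p = 0.031), without a level filter (adjusted p = 0.0033), with total-read scaling (adjusted p = 0.048) and with TPM scaling (adjusted p = 0.035). Among them the secreted cytokine GDF15 fell from 25.6 ± 2.9 to 11.3 ± 0.6 FPKM. In the BCL2 family 7 of 16 fell and 2 rose (the same adjusted over the list alone; adjusted p = 0.13, and 0.018 without a level filter). The proapoptotic member BAD, whose 3' UTR contains CTATGCAA, fell from 58.9 ± 2.2 to 33.3 ± 1.3 FPKM, and the antiapoptotic MCL1, whose 3' UTR contains CTATGCA, from 40.4 ± 0.4 to 30.0 ± 1.2 FPKM. FOXO targets fell in 10 of 22 and rose in 4, also adjusted over the list alone (adjusted p = 0.23, and 0.020 without a level filter). The death ligand TNFSF10, with CTATGCAA in its 3' UTR, fell from 7.54 ± 0.20 to 3.37 ± 0.21 FPKM. Heat shock proteins rose in 7 of 14 and fell in 2 (7 and 3 adjusted over the list alone; adjusted p = 0.21): the chaperonin HSPD1 rose from 48.1 ± 2.8 to 77.3 ± 2.6 FPKM, and HSPB1 fell from 1255 ± 12 to 754.1 ± 56.7 FPKM. Replication-dependent histones rose in 4 of 11 and fell in 1, also adjusted over the list alone (adjusted p = 0.21), although their mRNAs lack polyA tails and are close copies, so these values are uncertain.

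Mesenchymal transition genes split evenly, with 5 of 11 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.66). The matrix protein THBS1 rose from 18.7 ± 1.1 to 38.5 ± 2.8 FPKM, and TGFBI fell from 22.1 ± 1.1 to 12.8 ± 1.1 FPKM. Cholesterol synthesis genes fell in 8 of 24 and rose in 3 (10 and 4 adjusted over the list alone; adjusted p = 0.41), and fatty acid synthesis genes fell in 5 of 13 and rose in 1 (5 and 2 adjusted over the list alone; adjusted p = 0.32). The lipogenic transcription factor SREBF1, a member of both, fell from 96.8 ± 2.4 to 63.1 ± 4.0 FPKM. Integrated stress and unfolded protein response genes rose in 8 of 23 and fell in 5 (8 and 6 adjusted over the list alone; adjusted p = 0.52), and hypoxia genes rose in 4 of 16 and fell in 6 (4 and 7 adjusted over the list alone; adjusted p = 0.55). The stress-induced gene DDIT4, a member of both with CTATGCAA in its 3' UTR, fell from 396.3 ± 13.1 to 285.7 ± 12.3 FPKM. In the small interfering RNA machinery 4 of 10 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.55), and the list's mean and median differed in sign. TNRC6A, a partner of Argonaute with CTATGCA in its 3' UTR, fell from 4.19 ± 0.14 to 2.51 ± 0.17 FPKM. Of 20 markers of fibroblasts, endothelium and leukocytes only COL1A1 passed the level filter, at 4.93 ± 0.26 and 5.37 ± 0.46 FPKM (adjusted p = 0.25), so this list was not tested. COL1A1 was called higher under total-read scaling (adjusted p = 0.017), TPM scaling (adjusted p = 0.0053) and GC trend removal (adjusted p = 0.021).

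A single heptamer in 3' UTRs stood out in the genes that were lower after siSGK1. Among 15630 heptamers, CTATGCA had the strongest association with lower values (t = −16.1), and TATGCAA, shifted by 1 base, came next (t = −13.3). Genes with the joint octamer CTATGCAA in the 3' UTR (285) had a mean log2 change of −0.21 (SE 0.02). The mean was −0.09 (SE 0.01) for those with CTATGCA and no octamer (589), which may also hold TATGCAA elsewhere. It was −0.03 (SE 0.01) for those with TATGCAA and no CTATGCA (794), and −0.01 (SE 0.003) for those with none (8603). In these 4 classes 44.6%, 31.4%, 22.5% and 22.5% of genes were called lower. Of 363 genes with a searched 3' UTR that fell at least 1.5-fold, 80 had CTATGCA, or 9.15% of its 874 carriers, against a median of 2.47% and at most 5.93% for the carriers of 590 other heptamers of the same bases. CTATGCA was picked as the strongest heptamer on these same log2 changes, so this comparison gives a size and is not separate support. In SGK1 the heptamer lies in exons at 134173316 to 134173322 and 134174519 to 134174525 on chromosome 6. Each place is in 17 of 30 annotated transcripts, in coding sequence in 6 and 7 of them and in noncoding exons in the others, and neither is in a 3' UTR. In the other direction, GGAGAAA had the strongest association with higher values (t = 7.24), followed by TCGGAGA (t = 5.73) and CGGAGAA (t = 5.55); 6 heptamers towards lower and 5 towards higher values passed Bonferroni adjustment over all heptamers. Genes with the octamer TCGGAGAA (58), picked from these heptamers after the search, had a mean log2 change of 0.17 (SE 0.05), and 46.6% of them were called higher, against 17.4% of the 9862 genes with none of its sites.

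**Figure D4:**
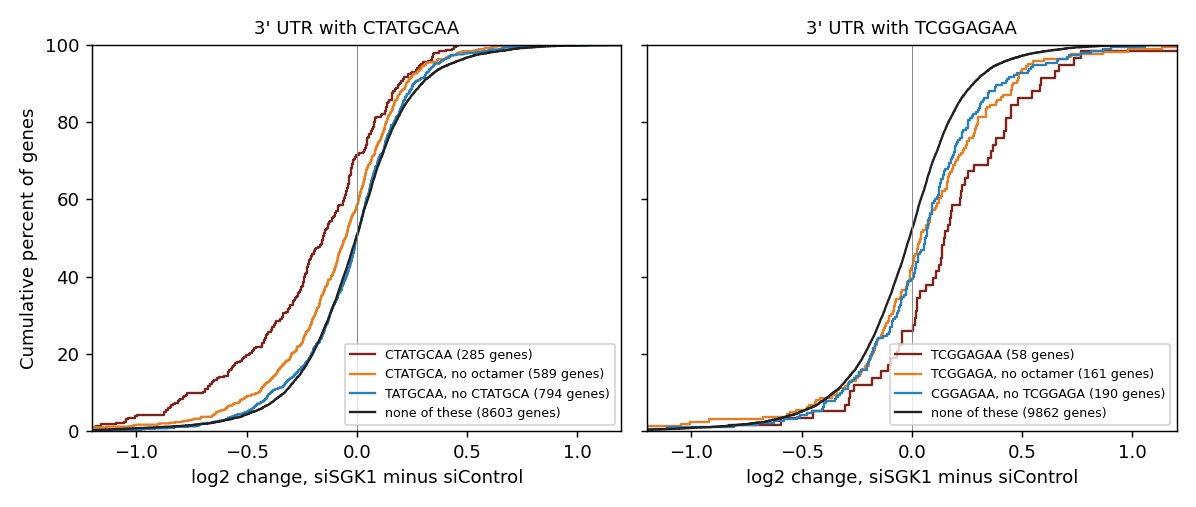
Cumulative percent of genes (vertical axis) against log2 change, siSGK1 minus siControl (horizontal axis), by the sites in each gene's longest 3' UTR for CTATGCAA (left) and TCGGAGAA (right). Curves for genes with CTATGCAA (285) lie left of those with none (8603), and curves for genes with TCGGAGAA (58) lie right of those with none (9862).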

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

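Scaling by total reads, TPM scaling, removal of a GC trend and leaving out genes with a 3' UTR site were chosen after seeing the data; the other settings were planned. SGK1 was lower and called in all 22 other fits that tested it; with a mean FPKM filter of at least 5 it gives no value. The count of called genes stayed within 1.5 times of 4852 in all 23 other fits, and leaving out 1 library gave 3773 (without siControl replicate 3) to 4345. A similar count need not mean the same genes. Of 6816 genes called under TPM scaling 3315 were among the 4852, as were 3689 of 5855 under total-read scaling. Without a level filter 3320 of 3764 were. Fewer tested genes lowered the counts with the filter of at least 5: 1282 higher, and 135 higher and 254 lower at 1.5-fold. Total-read scaling gave 4309 higher and 1546 lower (537 and 265 at 1.5-fold), and TPM scaling 5645 and 1171 (925 and 254), since both shift all genes upwards relative to siControl. Quantile normalization called 5 lists lower instead of 9 and turned the log2 change of MT-ND6 to 0.038, of MT-CO3 to 0.052, of RPS18 to 0.0024 and of RPS2 to 0.057. None of these genes was called after it (adjusted p = 0.42, 0.33, 0.94 and 0.062), so these values near 0 are not rises. The cause was not tested. With an estimated correlation camera called 0 lists, 0 higher and 0 lower, against 13 with the preset one; fry, which does not compare a list with other genes, called 22, 8 higher and 14 lower. A higher correlation within the list does not account for every lost call: that of the DNA replication list was estimated at −0.02, below the preset 0.01. Without the genes that have a site of either octamer, 3837 of 9967 genes were called and the list of SGK and AKT kinases alone lost its call. Voom on the recovered reads called 5379 genes, 4709 of them shared with the 4852. Removal of the GC trend called 5455 genes, 4415 of them shared.

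The values gave no clear sign that replicate numbers pair the samples: the deviations of same-numbered libraries correlated at 0.12, 0.01 and −0.10 across genes, and not every library correlated best with its own number. The labels do not say whether a number marks a shared day, and 3 libraries per group are too few to settle it. With the replicate number as a block, 4560 genes were called, 4376 of them among the 4852. Over all combinations of a list and a setting, a call was lost in 28, gained in 17 and unchanged in 629. The setting with an estimated correlation alone ended all 13 calls. Over all combinations of a named gene and a setting, a call was lost with the sign unchanged in 14 and gained in 3. The sign changed and the call was lost in 4, and the outcome was the same in 2740. The 14 include AGO2 with total-read scaling (adjusted p = 0.17) and TPM scaling (adjusted p = 0.44). They also include AGO2 without siControl replicate 3 (adjusted p = 0.056) and without siSGK1 replicate 4 (adjusted p = 0.053). Depth limits SGK2 (0 to 2 reads) and genes below 1 FPKM.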

Other observations

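The tests on the low control library, scaling, the transfected RNA, shared keratin reads, the microRNA and the second octamer were chosen after the results they bear on had been seen at least in part; the removal of a GC trend was likewise added after the data had been seen, and the list of YAP targets was written after CYR61 and THBS1 had been seen and leaves them out. The heptamer search was written down before it was run. The test on scaling replaced others whose outcome a single factor per library fixes. All patterns weighed here were noticed in these data, so any explanation is a hypothesis.

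The values of the neighbours of AC011346.1 and SPINK13 on chromosome 5 were looked up after these 2 genes had been seen, and they went different ways. SPINK6, the nearest upstream gene of AC011346.1 on the same strand (148202794 to 148215137), went from 224.3 ± 6.5 to 409.3 ± 13.8 FPKM (SD, n = 3 each; log2 change 0.87, adjusted p = 9.28e-06). SPINK5, further upstream, measured 7.02 ± 0.21 and 6.96 ± 0.19 FPKM (adjusted p = 0.87). SPINK7, downstream, went from 2.00 ± 0.31 to 1.45 ± 0.10 FPKM (adjusted p = 0.025), and FBXO38, beyond it, measured 3.48 ± 0.41 and 3.20 ± 0.19 FPKM (adjusted p = 0.37).

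The 3' UTR heptamers offer a candidate explanation for part of the changes: off-target silencing through the seed of an siRNA. The strongest heptamer towards lower values, CTATGCA, reached t = −16.14, and all 8 heptamers shifted from it by 1 base ranked in the strongest 1% of 15630. A 3' UTR with CTATGCA also holds such shifted heptamers, unless the site lies at its end, so these ranks are not separate support. Genes with TATGCAA and no CTATGCA were called lower as often as genes with none (22.5% each). Its presence in SGK1 is weak evidence, since 30.6% of all heptamers occur in an SGK1 transcript, and a microRNA with the same seed, such as miR-153, cannot be told apart because polyA libraries do not count it; its host genes PTPRN and PTPRN2 had 403 reads in siControl and 243 in siSGK1. For higher values, genes with TCGGAGAA exceeded genes with a heptamer of it and no octamer by 0.1269 (SE 0.05), and genes without any site by 0.1995. But the octamer and both comparisons were picked on these same values, and the strongest heptamer was GGAGAAA. Whether a seed of the control siRNA acted therefore stays open. Of the 363 genes with a searched 3' UTR that fell at least 1.5-fold, 258 have no site of the first octamer. Most genes lack one: 8603 of the 10271 searched. Falls of at least 1.5-fold made up 14.74% of genes with CTATGCAA and 6.452% of those with CTATGCA and no octamer. They made up 3.149% of those with TATGCAA and no CTATGCA and 2.999% of those with none. CTATGCA was picked on these same changes. Only these sites in the longest 3' UTR were counted, so a gene without one is not shown to escape silencing. Of the 13 lists called with the preset correlation (0 with an estimated one), 12 stayed called without site-bearing genes. Secondary effects of silenced genes stay open.

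The higher interferon response genes do not rest on the control library with the lowest IFI6: without each control library in turn, the largest adjusted p of the list was 3.216e-09 with the preset correlation (adjusted p = 0.26 with an estimated one over all libraries). A single factor per library moves all genes alike and cannot give the change of the list relative to the other tested genes, and under quantile normalization, which can act differently by level, that change was 0.7177 on the log2 scale (SE over members 0.10), which argues against scaling. A response to the transfected RNA cannot be told apart from a response to the loss of SGK1, because each group received a single kind of siRNA. IFNB1 and IFNL1 together had 4 reads in the 3 siSGK1 libraries and 0 in siControl, too few to decide. A response to the loss of SGK1 remains untested against it.

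Lower keratinocyte differentiation genes together with higher mitosis genes may reflect a difference in cell density at harvest, an effect of SGK1 loss on differentiation, or an off-target effect. A trend on gene length or GC is argued against as the source of these 2 calls. The largest adjusted p of the 2 lists with either trend removed was 8.743e-11 with the preset correlation. Such trends were present across genes: the log2 change had a Spearman correlation of −0.24 with GC and 0.08 with length. With mean log2 FPKM the correlation was −0.16, a trend that these fits did not remove. Before any correction, neither list was called with an estimated correlation (adjusted p = 0.23 for each). Shared reads between keratin or SPRR copies are argued against only for the other members: without these families all 14 tested members fell, with a mean log2 change of −0.6769 relative to other genes (camera p = 2.10e-09, and 0.014 with an estimated correlation). Both p-values are for this list alone and are unadjusted, unlike the 0.23 of the full list. Since 27 of 28 members of the full list fell, this outcome was largely fixed beforehand. It decides nothing for the keratin and SPRR genes themselves. Targets of YAP, which is active at low density, went both ways (6 of 18 rose and 6 fell, with a mean of 0.01233 relative to other genes), which leaves lower density open. Some of these targets have sites of the first octamer. PTPN14 (log2 change −1.26) and NT5E (−0.50) contain CTATGCA, and ASAP1 (−0.41) and AMOTL1 (0.34) contain TATGCAA. Among targets without a site, the largest rises were ANKRD1 (1.06), F3 (0.73) and LATS2 (0.51). The largest falls among them were MYOF (−0.40), GADD45A (−0.33) and FOXF2 (−0.26). The effect of SGK1 loss was not separated from the other explanations.

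Over the 10 splits of the 6 libraries into 3 and 3, the real one called 4852 genes and the highest of the others called 0; 1 split, the real one, reached that count, and 10 splits are too few for a share under 0.05.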
